A study of Mus musculus with 22 samples.

How the data were processed

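Biotin-labelled total RNA was read on Affymetrix MG-U74v2 arrays, a mouse set split over 3 chip types (A, B and C) on which each transcript is read by a probe set. The 22 arrays carried 8 numbered RNA preparations, called RNA samples here: 2 from mammary tumours labelled PEA3-null, 3 from tumours wild type for PEA3 and 3 from normal glands of the FVB strain. Chips A and B held all 8, and chip C held 1 PEA3-null, 2 wild-type and 3 normal samples. Groups and replicate numbers were taken from the labels. The tumour RNA is described as pooled, and the normal samples are titled as pools. All arrays of a group share the submitters' sample identifier, and the series description counts 3 samples, with the 22 arrays as replicates. Replicates may therefore be repeat preparations of the same material, and the p-values measure the spread between preparations, not between animals.

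The deposited values were linear probe set intensities made with MAS5, per the labels, which give no version or settings. In the deposited values the 2% trimmed mean of every array lay between 1500.28 and 1501.06, so each array had been scaled to a common level. The deposited instrument files hold settings as text (other, no measurement), and only scan day, chip lot and wash record were taken from them.

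Each array was rescaled to a 2% trimmed mean of 500, 32 was added, and log2 was taken. Folds below come from these log2 values, so they understate the change of dim probe sets. The 198 control probe sets, 66 per chip type, were left out. Probe sets with a scaled signal of at least 150 on at least 2 arrays of a chip type were tested, which left 8820 on chip A, 10455 on chip B and 8967 on chip C. Of 36701 probe sets, 29131 had 1 gene symbol in the platform annotation, 724 had several and 6846 had none, and 29044 matched the RefSeq table of assembly GRCm38.p6 by gene identifier. Only probe sets with 1 symbol are named. The files give no probe positions, so no coordinates are given.

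Groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a mean-variance trend), per chip type, in a fit of all 3 groups that share an estimate of the spread. Tests were two-sided, with Benjamini-Hochberg adjustment over the probe sets of the chip types that entered and a threshold of 0.05. Comparisons with PEA3-null tumours used chips A and B, because chip C held 1 such array, and wild-type tumours were compared with normal glands on all 3 chip types. The number of arrays limits the precision.

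The 26 gene lists were tested with camera at a preset inter-gene correlation of 0.01, on 11743 genes of chips A and B, each read by its probe set with the highest mean log2 signal. The adjustment covered 78 tests. At this setting 29 passed. With an estimated correlation 0 camera tests passed, 19 had an unadjusted p under 0.05, and the lowest adjusted p was 0.0788. With fry, which asks whether the genes of a list move on balance one way and compares them with no other genes, 40 passed, 26 of them among the 29.

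Named genes are the 10 largest rises and the 10 largest falls of each comparison among probe sets past the threshold whose groups did not overlap, with Etv4, Etv1, Etv5, Erbb2 and Ly6a, and up to 4 members of each list with the largest change. Groups, tests, lists, this rule and the alternatives, except those said to be added later, were set before the data were examined. The alternatives concerned array scaling, the added constant, the filter, the arrays in the fit, the variance model, replicate numbers as a block, chip types, scan day, a fold minimum and each RNA sample left out in turn.

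The fits were tested on simulated arrays with 200 changed probe sets, each probe set with the same spread in all groups. In the data the normal glands varied less than the tumours on chips A and B (median log2 SD on chip A 0.21 against 0.32). The simulated share of false calls therefore does not carry over to the real calls between the genotypes. Between the genotypes, in 18607 simulated probe sets, 2.08% of those changed by 1 on the log2 scale and 36.8% of those changed by 2 were recovered, and 4 of 41 calls were false. For wild-type tumours against normal glands the shares were 5.15% and 31.9%, and for PEA3-null tumours against normal glands 7.22% and 38.7%. A simulated list shifted by 1 was recovered in both comparisons that held it, and camera called 0 of 25 other lists in each of the 3 comparisons. The simulated genes varied independently, whereas the estimated correlation in the data was 0.18 for interferon and 0.28 for milk genes. The simulation therefore does not show how often camera at the preset correlation calls lists of correlated genes falsely.

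On chip A the 5 tumour arrays shared a scan day. On chip B the PEA3-null arrays were scanned on separate days from each other and from the wild-type arrays. Their chip lot also differed from that of the wild-type arrays there. Tumour and normal arrays of a chip type shared no scan day, so scan day and tissue cannot be told apart. The chip A wash of normal glands 1 and 2 was recorded as aborted.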

Results

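RNA was measured in mouse mammary tumours induced by the Her2/Neu transgene, which encodes the ErbB2 receptor, and in normal FVB mammary glands. The tumours came from mice labelled PEA3-null or wild type for PEA3, a transcription factor of the ETS family encoded by Etv4. There were 2 PEA3-null, 3 wild-type and 3 normal RNA samples. Between 6939 and 8430 probe sets per array reached a scaled signal of 150. On chip A, arrays correlated across probe sets at 0.959 to 0.963 within normal glands, 0.901 to 0.913 within wild-type tumours and 0.882 between the PEA3-null samples. Pairs of different tumour genotype reached 0.874 to 0.913 there, and probe sets are not independent replicates. The labels state sorting for the surface marker Sca-1 for every group.

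Etv4 signal was first set against the genotype label. The arrays labelled PEA3-null did not read lower for Etv4. The Etv4 probe set that was higher in tumours read 394 ± 167 (SD, n = 2) in PEA3-null tumours, 380 ± 34.6 (SD, n = 3) in wild-type tumours and 149 ± 31.6 (SD, n = 3) in normal glands. Its log2 difference between the genotypes was -0.01 (SE 0.34, limma adjusted p = 0.998). The other Etv4 probe set differed by -0.22 (SE 0.37, limma adjusted p = 0.875). A probe set outside the deleted part checks nothing, and neither the deleted part nor the probe positions are given in the sources used here. The genotypes are therefore named by their labels.

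Etv5, a close relative of Etv4, was 11.7-fold higher in wild-type tumours than in normal glands, at 4589 ± 478 against 364 ± 50.9 (SD, n = 3 each, limma adjusted p = 1.53e-07). It read 4709 ± 1519 (SD, n = 2) in PEA3-null tumours, a log2 difference of 0.00 from wild-type tumours (SE 0.24, limma adjusted p = 0.998). Erbb2, read on chip C, was 2.02-fold higher in wild-type tumours (3854 ± 420, SD, n = 2) than in normal glands (1884 ± 71.6, SD, n = 3, limma adjusted p = 0.00962). The lone PEA3-null array read 4837 for Erbb2. Without probe positions it cannot be told whether this probe set reads the transcript of the transgene. No tested probe set carried Etv1 or Ly6a, the gene of Sca-1, as its only symbol.

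**Figure D1:**
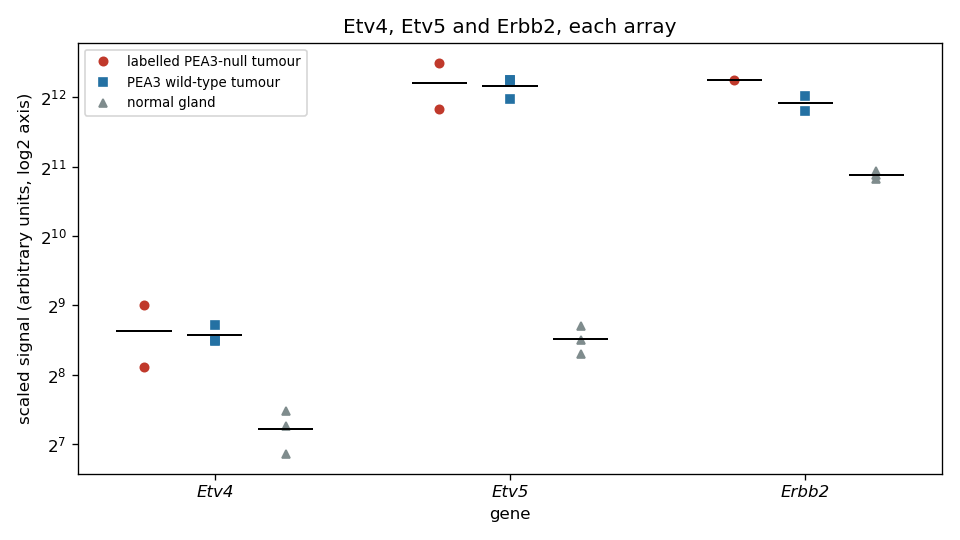
Scaled signal (arbitrary units, log2 axis) of Etv4, Etv5 and Erbb2, with a point for each array and a bar for each group mean. Etv4 averages 394 in PEA3-null tumours, 380 in wild-type tumours and 149 in normal glands.

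The comparison of PEA3-null with wild-type tumours asks how Her2/Neu tumours labelled as lacking PEA3 differ from those that have it. Several interferon-induced genes were higher in the PEA3-null tumours. Ifit3, an antiviral gene, was 5.94-fold higher (log2 2.57, SE 0.35, limma adjusted p = 0.022). Usp18, which removes the ubiquitin-like protein Isg15, read 2135 ± 62.1 (SD, n = 2) against 415 ± 88.6 (SD, n = 3), and was 4.91-fold higher (limma adjusted p = 0.0112). Oasl2 was 3.73-fold higher (limma adjusted p = 0.00236), and Gbp3, an interferon-induced GTPase, 3.50-fold higher (limma adjusted p = 0.022). Among probe sets past the threshold the largest rise was that of Cpe, which encodes the hormone-processing enzyme carboxypeptidase E, at 1850 ± 535 (SD, n = 2) against 179 ± 45.7 (SD, n = 3, 8.87-fold, limma adjusted p = 0.000995).

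Of 29 measured genes of interferon response and antigen presentation, 9 rose, 0 fell and 20 did not pass, and 19 rose when adjusted over the list alone. Their median log2 difference was 0.84 (camera adjusted p = 1.08e-21, adjusted p = 0.0788 with an estimated correlation). On chip A alone, with only the tumour arrays, which share a scan day, the median was 0.77 over 25 genes (camera adjusted p = 2.78e-22, adjusted p = 0.427 with an estimated correlation), a fit added after seeing the data. The other 5 genes that rose were Bst2 (log2 1.65), Isg15 (1.62), Tap1 (1.29), Irf7 (1.16) and Psmb8 (1.09), named after their values were seen. The class II genes Cd74 and H2-Aa did not pass, with log2 differences of 0.68 and 0.66.

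**Figure D2:**
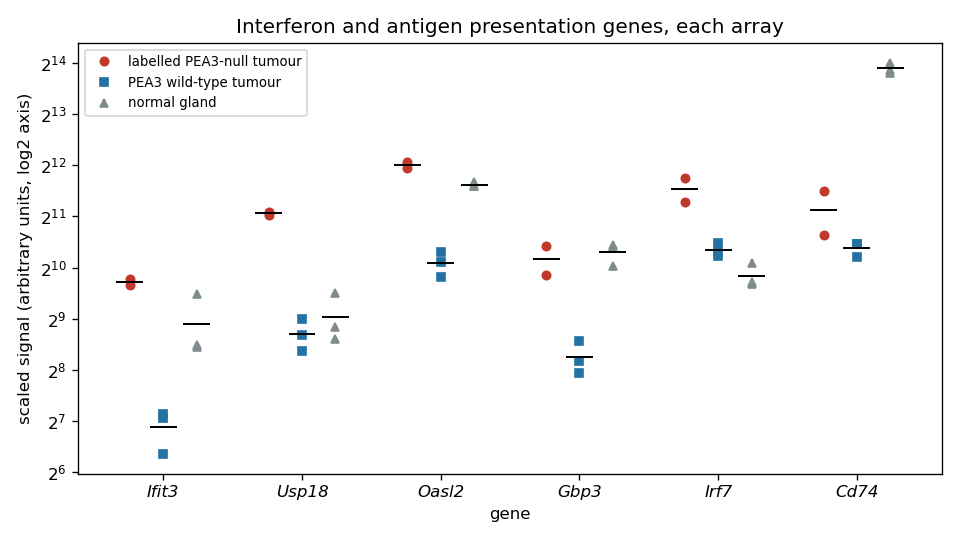
Scaled signal (arbitrary units, log2 axis) of 6 genes of the interferon and antigen presentation list, with a point for each array and a bar for each group mean. Usp18 averages 2135 in PEA3-null and 415 in wild-type tumours, while Cd74 is highest in normal glands.

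Other genes that rose in PEA3-null tumours were the kinase gene Tec (5.28-fold), the sialyltransferase gene St6galnac2 (4.18-fold) and the ephrin gene Efnb1 (4.08-fold). Car3, a carbonic anhydrase of fat and muscle, and Tnnc2, a troponin of fast skeletal muscle, rose 5.58-fold and 4.03-fold. Car3 read 767 in PEA3-null sample 2, 218 in sample 1 and at most 54.8 in wild-type tumours. Acta1, skeletal muscle actin, read 1405 in sample 2 and 175 in sample 1, and did not pass (limma adjusted p = 0.388). Genes that fell included Usp22 (log2 -2.54), BC006965 (-2.46), Rtkn (-2.28, also lower at its other probe set), Glb1l2 (-2.20), Plbd2 (-2.15), Miga2 (-1.98), Iqsec1 (-1.95), the chemokine gene Ccl24 (-1.82), Ppp1r16a (-1.72) and the splicing regulator gene Mbnl2 (-1.32). Of these falls, all but Rtkn and Miga2 were read on chip B, as were the rises of Oasl2 and Efnb1. On that chip, scan day and chip lot differed with the genotype and cannot be told apart from it. The other tested probe sets of Usp22, BC006965, Glb1l2 and Plbd2 had the opposite sign, and those of Iqsec1 and Mbnl2 were divided.

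Adipocyte genes (1 of 27 rose, median 0.21, camera adjusted p = 0.00374), lymphocyte genes (0 of 21 rose, median 0.27, camera adjusted p = 0.0124) and luminal epithelial genes (0 of 23 rose, median 0.15, camera adjusted p = 0.0396) were shifted upward as lists. Adjusted over the list alone, 4, 2 and 4 genes rose and 1, 0 and 1 fell. With an estimated correlation the adjusted p was 0.474 for the adipocyte, 0.474 for the lymphocyte and 0.33 for the luminal list. None of them passed with fry either (fry adjusted p = 0.144, 0.202 and 0.0666). On chip A within the shared scan day the 3 lists did not pass (camera adjusted p = 0.166, 0.166 and 0.061). There the list of erythroid genes, 3 of them measured, passed downward (median -0.88, camera adjusted p = 0.00133, adjusted p = 0.683 with an estimated correlation). It did not pass on chips A and B (camera adjusted p = 0.0715). Slc4a1, the erythroid gene that differed upward (log2 0.94), missed the signal filter without the normal arrays and dropped out of the chip A list. In the fit without PEA3-null tumour replicate 2 the adipocyte, lymphocyte and luminal lists did not pass (camera adjusted p = 0.278, 0.56 and 0.427). In the fit without PEA3 wild-type tumour replicate 1 the lymphocyte and luminal lists did not pass (0.0513 and 0.0884). The luminal list also missed the threshold without PEA3-null tumour replicate 1 (0.0771), without PEA3 wild-type tumour replicate 2 (0.134) and without PEA3 wild-type tumour replicate 3 (0.0536). Genes described as targets of the PEA3 subfamily did not pass (18 measured, median 0.07, mean -0.01, camera adjusted p = 0.723; on chip A within the shared scan day 14 measured, median -0.38, camera adjusted p = 0.225), nor did ETS factors (21 measured, median 0.00, mean -0.03, camera adjusted p = 0.92).

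In all, 37 of 19275 probe sets passed, 23 higher and 14 lower, and 2031 had an unadjusted p under 0.05. The directions differed by chip type, with 17 higher and 3 lower on chip A and 6 higher and 11 lower on chip B. In the later fit of chip A within the shared scan day, 6 were higher and 0 lower. The fit shares the spread of the normal glands, whose median log2 SD on chip A was 0.21 against 0.32 in each tumour group. The standard errors and p-values given above between the genotypes are therefore too small on average. With only the tumour groups in the fit, 5 probe sets were higher and 0 lower. The count depended on the fit, for reasons not tested: it was 5 with only the tumour groups in the fit, 3 with array weights, 4 without the variance trend and 6 on chip A within the shared scan day. Without normal gland 1, 2 or 3 it was 9, 13 or 6, without wild-type tumour 1, 2 or 3 it was 3, 6 or 18, and without PEA3-null tumour 1 or 2 it was 241 or 48, each from a lone sample assumed to vary like the other groups. The balance of directions turned over in these fits, with 55 higher and 186 lower without tumour 1 and 15 higher and 33 lower without tumour 2, and with chip C added, with 27 higher and 36 lower. Of the 20 genes named by size of change, Cpe passed in all 25 alternative fits that tested it, Oasl2 missed the threshold in 1 of 23, and the others missed it in 5 to 18.

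The comparison of wild-type tumours with normal glands asks what sets Her2/Neu tumours apart from the gland. Tumours had far lower signals for genes of skeletal muscle, fat and connective tissue, and higher signals for genes of luminal epithelium, milk and the cell cycle. The water channel gene Aqp5 was 163-fold higher in tumours (45710 ± 4481 against 261 ± 116, SD, n = 3 each, limma adjusted p = 4.08e-09), the cartilage collagen gene Col9a1 186-fold and the neuropeptide gene Npy 94.3-fold. Also higher were 2900060B14Rik (87.8-fold), Car6, a secreted carbonic anhydrase (81.3-fold), the mitotic spindle gene Spag5 (72.1-fold), the glycolytic aldolase gene Aldoc (57.2-fold), Il20rb (50.8-fold), Mia (43.0-fold) and Scrg1 (42.3-fold). Of these genes all but Aqp5, Aldoc and Il20rb read below 150 in normal glands, so their folds depend on the added constant and their order is not measured. The ratio of 3' to 5' GAPDH control signal, which rises as RNA degrades, was 2.58 to 6.08 in normal glands and 0.91 to 1.25 in tumours, over all chip types, and this difference accompanied every gene group that follows. The same ratio for actin overlapped, at 1.28 to 2.14 and 1.14 to 1.66.

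Of 20 skeletal muscle genes 17 fell and 0 rose, 18 falling when adjusted over the list alone (median -5.53, camera adjusted p = 1.23e-15, adjusted p = 0.0788 with an estimated correlation). Myh4, a fast myosin heavy chain, read 35511 ± 2894 in normal glands and 52.8 ± 54.0 in tumours (SD, n = 3 each, limma adjusted p = 3.22e-07), and Acta1 (-8.15), Tnnt3 (-7.48) and Myl1 (-7.25) were also among the large falls. Such falls to tumour signals near or below 150 depend on the added constant, so their order is not measured. A probe set of Atp2a1 that did not enter the list test fell by 8.48. Of 27 adipocyte genes 22 fell and 2 rose, 24 falling when adjusted over the list alone (median -3.58, camera adjusted p = 7.74e-14, adjusted p = 0.0788 with an estimated correlation), among them Car3 (-8.21), the adiponectin gene Adipoq (-6.30), Retn (-6.23) and the lipoprotein lipase gene Lpl (-6.11). Fatty acid synthesis genes fell (9 of 16, with 2 rising and 10 falling when adjusted over the list alone, median -1.52, camera adjusted p = 6.12e-05, adjusted p = 0.179 with an estimated correlation), with Fasn at -4.74 and Acaca at -4.47. Fatty acid oxidation genes fell (12 of 13, also 12 when adjusted over the list alone, median -1.80, camera adjusted p = 4.60e-09, adjusted p = 0.0788 with an estimated correlation), with Cpt1a at -3.38. Of 22 oxidative phosphorylation genes 11 fell, 13 when adjusted over the list alone (median -0.53, camera adjusted p = 0.000335, adjusted p = 0.513 with an estimated correlation).

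Of 30 fibroblast and matrix genes 23 fell and 1 rose, 25 falling when adjusted over the list alone (median -2.36, camera adjusted p = 7.19e-13, adjusted p = 0.0788 with an estimated correlation), among them Gsn (-5.46), Dpt (-4.48) and the decorin gene Dcn (-4.13). Of 18 endothelial genes 13 fell, 14 when adjusted over the list alone (median -1.94, camera adjusted p = 2.04e-06, adjusted p = 0.0788 with an estimated correlation), with the VE-cadherin gene Cdh5 at -4.14 and Vwf at -3.06. Of 21 lymphocyte genes 14 fell, 19 when adjusted over the list alone (median -1.69, camera adjusted p = 3.29e-06, adjusted p = 0.176 with an estimated correlation), with Thy1 at -3.40 and Cd79b at -2.97. Of 16 basal and myoepithelial genes 5 fell, the same number when adjusted over the list alone (median -0.51, camera adjusted p = 0.0289, adjusted p = 0.176 with an estimated correlation), with the smooth muscle actin gene Acta2 at -2.77. That list did not pass without PEA3 wild-type tumour replicate 2 (camera adjusted p = 0.0543). Of 29 interferon and antigen presentation genes 12 fell and 2 rose, 14 falling when adjusted over the list alone (median -0.71, camera adjusted p = 0.000519, adjusted p = 0.444 with an estimated correlation), among them Cd74 (-3.49), H2-Aa (-3.03) and Gbp2 (-2.55).

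Luminal genes rose (15 of 23, with 3 falling, the same when adjusted over the list alone, median 1.35, camera adjusted p = 4.62e-05, adjusted p = 0.0788 with an estimated correlation), among them the tight junction genes Cldn3 (4.17) and Cldn7 (3.36), while the keratin gene Krt19 fell by 5.44. Milk and secretory genes rose (14 of 20, with 3 falling, the same when adjusted over the list alone, median 1.22, camera adjusted p = 0.000373, adjusted p = 0.444 with an estimated correlation), with Wfdc18 at 4.84 and the alpha-lactalbumin gene Lalba at 4.23, while Glycam1 fell by 5.34. Of 37 cell cycle genes 19 rose and 0 fell, 21 rising when adjusted over the list alone (median 1.12, camera adjusted p = 7.75e-07, adjusted p = 0.166 with an estimated correlation), with Cks2 at 3.85 and Cdk1 at 3.35. Lists that did not pass still held genes that changed, such as the immediate early gene Ier3 (4.68), Notch4 (3.69), the ETS factor gene Spdef (3.27), Xbp1 (2.77), Hk2 (-4.47) and Aldh1a1 (-3.99). The other tested probe sets of Notch4, Acta2 and H2-Aa, on chip C, had the opposite sign and did not pass.

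**Figure D3:**
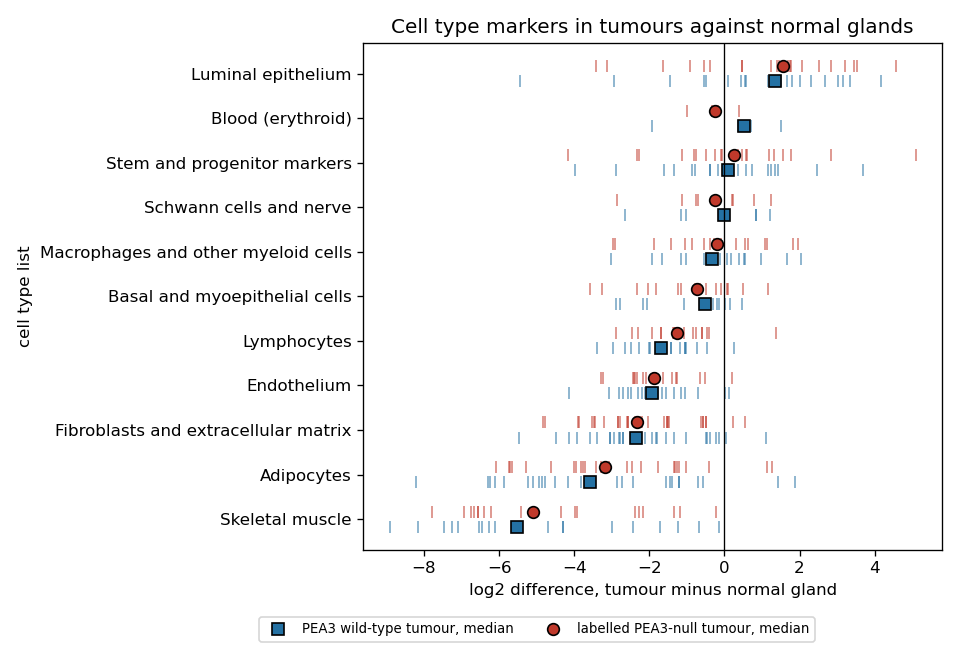
Log2 difference, tumour minus normal gland, of each measured gene of the cell type lists (ticks) with the list median (square for wild-type, circle for PEA3-null tumours). Skeletal muscle has the lowest medians, -5.53 and -5.09, and luminal epithelium the highest, 1.35 and 1.56.

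In all, 5876 of 28242 probe sets passed, 2971 higher and 2905 lower in tumours. Without normal glands 1 and 2, whose chip A wash was aborted, 2093 passed, in a fit added after seeing the data that leaves a lone normal sample assumed to vary like the other groups. That fit dropped both glands on every chip type. It kept gland 3, which had the highest GAPDH ratio of the normal samples on chips A, B and C (5.25, 5.68 and 6.08). Tumour and normal arrays shared no scan day on any chip type, so scan day and tissue cannot be told apart.

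The same comparison for PEA3-null tumours asks which of these differences appear when PEA3 is labelled as missing. Muscle, fat and stromal genes were again lower, and luminal, milk and cell cycle genes higher. Col9a1 was 124-fold, Aqp5 120-fold, Car6 51.2-fold, Aldoc 44.5-fold and Npy 41.4-fold higher, and Notch4, a Notch receptor gene, was 34.1-fold, Sdc4 32.8-fold, Shf 31.9-fold and Ncald 29.6-fold higher. Col9a1, Car6, Npy, Sdc4 and Shf read below 150 in normal glands, so these folds depend on the added constant. Among the largest falls were those of Myh4 (-7.78), Atp2a1 (-7.73), Actn3 (-6.93), Pygm (-6.69) and Mybpc1 (-6.61). The GAPDH ratio of tumours and normal glands differed as above, beside each of these groups.

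Skeletal muscle (18 of 20 fell, median -5.09, camera adjusted p = 3.28e-16), adipocyte (22 of 27 fell and 2 rose, median -3.19, camera adjusted p = 9.29e-14), fibroblast (24 of 30 fell, median -2.32, camera adjusted p = 7.74e-14), endothelial (15 of 18 fell, median -1.87, camera adjusted p = 8.87e-07) and fatty acid oxidation genes (12 of 13 fell, median -1.83, camera adjusted p = 4.60e-09) fell as lists. Adjusted over the list alone, 18, 24, 26, 15 and 12 genes fell. Luminal genes rose (15 of 23, with 3 falling, also when adjusted over the list alone, median 1.56, camera adjusted p = 5.36e-06). With an estimated correlation the adjusted p was 0.0788 for each of these 6 lists. Milk genes rose (13 of 20, with 2 falling, median 1.11, camera adjusted p = 0.000259, adjusted p = 0.444 with an estimated correlation), and so did cell cycle genes (19 of 37, 22 when adjusted over the list alone, median 1.07, camera adjusted p = 1.15e-06, adjusted p = 0.167 with an estimated correlation). Lymphocyte (10 of 21 fell and 1 rose, median -1.25, camera adjusted p = 0.000266), fatty acid synthesis (9 of 16 fell and 2 rose, median -1.56, camera adjusted p = 0.000259), oxidative phosphorylation (11 of 22 fell, median -0.54, camera adjusted p = 0.000119) and basal genes (6 of 16 fell, median -0.72, camera adjusted p = 0.0173) fell as lists. With an estimated correlation these had an adjusted p = 0.301, 0.223, 0.491 and 0.166. Interferon and antigen presentation genes did not pass as a list, with 10 rising and 6 falling of 29 (median 0.36, camera adjusted p = 0.319). Usp18 (2.01) and Irf7 (1.66) rose, and Cd74 fell by 2.80.

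In this comparison 4750 of 19275 probe sets passed, 2361 higher and 2389 lower. Without normal glands 1 and 2 the count was 1709, again in a fit added after seeing the data, and scan day and tissue cannot be told apart here either.

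Of the calls against normal glands on chips A and B, 3693 probe sets passed for both tumour genotypes with the same direction (1869 higher, 1824 lower) and 2 with opposite directions. Independent lists of these sizes would share 324 higher and 313 lower probe sets, and a simulation of tumours without effects made at most 1 call per direction, so it gives no count to compare. The log2 differences correlated at 0.859 across probe sets, which are not independent replicates, against 0.447 in that simulation, where the shared normal arrays alone create a correlation. Their covariance was 1.14 against 0.106. The 3 normal samples do not give each genotype 2 of its own, so the controls were not divided. Part of the excess over independent lists may come from sharing them. The simulation gave all groups the same spread, although normal glands varied less than tumours on these chips.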

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

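All tests of explanations in this part were chosen after the result was seen, except the counts over other divisions of the samples, which were planned. The criteria for RNA integrity and array background were revised, and the test of lymphocyte and myeloid markers was divided, after their values were seen. The tumour-to-normal difference differed between the genotypes at 37 probe sets, tested directly between the tumour groups. The 10 divisions of the 5 tumour samples into 2 and 3, of which 1 gave as many, are too few for a share under 0.05. The real one gave 37 and the highest other 3 in limma, but at an unadjusted p under 0.05 the real one gave 2031 and another gave 2339. For wild-type tumours against normal glands the 10 divisions, of which 1 gave as many, are too few as well. The real division gave 5876 and the highest other 0, with 9019 and at most 985 at an unadjusted p under 0.05. Every other division mixed tumour and normal samples in both groups. The tissue difference then entered the spread, so low counts were to be expected there and the contrast shows little.

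As a list the interferon and antigen presentation genes were higher in PEA3-null tumours, with 9 of 29 past the threshold and an adjusted p = 0.0788 with an estimated correlation. Scan day is argued against, because on chip A, scanned on a single day for tumours, the list mean was 0.957 higher (SE 0.185) and both PEA3-null samples lay above every wild-type sample, and so is a single PEA3-null sample, since the lower of them exceeded the wild-type mean by 0.971 (wild-type SD 0.227). More myeloid cells are argued against as the whole source: 19 markers outside the list differed by -0.0324 (SE 0.23), less than the list by 1.04 (SE 0.236), with abundant ones going both ways without passing (Lyz2 -0.93, C1qa -0.08, Cd14 0.60, Ctss 0.82, Lgals3 0.84). More lymphocytes stay open, as a part or as the whole source. On few samples, 21 markers differed by 0.43 (SE 0.195), less than the list by 0.578 (SE 0.191). The markers were dimmer, with a mean log2 signal of 7.39 to 8.17 in tumours against 9.84 to 11.04 for the list. The added constant understates the change of dim genes more, so this comparison cannot decide. Cd79b (1.59), Cr2 (1.33), Ptprc (1.32) and Jchain (1.13), none past the threshold, differed by as much as the list. RNA quality was not tested: on chip A the GAPDH ratio was 0.978 to 0.982 in PEA3-null and 1.15 to 1.23 in wild-type tumours. The actin ratio there overlapped (1.24 to 1.26 and 1.21 to 1.66), as did the GAPDH ratio on chip B. PEA3 itself, and other differences between the mice or their pools, such as exposure to infection, stay open and untested.

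The fall of adipocyte, skeletal muscle and stromal genes in tumours is the next pattern. RNA integrity stays open: the median of 95 such genes (-2.70) lay below that of 100% of 10000 random lists matched on mean signal, but this restates the fall, and without probe positions it cannot separate integrity from tissue. A single dilution common to all non-epithelial tissue is argued against as the only source, by the medians of the larger lists. The medians of 8 lists spanned 6.06 on the log2 scale (permutation p = 0.0003), from erythroid genes (4 measured, 0.53) to skeletal muscle (-5.53). So the erythroid genes, which read blood in the sample, set the upper end. The permutation deals genes as if they were independent, and the added constant limits the fall of dim genes, so the permutation alone cannot decide. Macrophage and myeloid genes (19 measured, 3 rose and 3 fell) had a median of -0.34. The medians were -2.36 for fibroblast, -3.58 for adipocyte and -5.53 for skeletal muscle genes. The myeloid genes were not dim on average, with a mean log2 signal of 9.68 to 9.90 in normal glands. Scan day and chip lot cannot be told apart from tissue, because 0 scan days held tumour and normal arrays of a chip type. Different amounts of fat and muscle in the dissected tissue stay open and untested.

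The Etv4 signal was not lower in PEA3-null tumours. Array background is argued against for both Etv4 probe sets in tumours by their level. The probe set with the lower mean signal read 276 to 513 in PEA3-null and 360 to 420 in wild-type tumours. The other read 470 to 734 and 367 to 954. The median scaled signal of the tumour arrays on chip A was 196 to 232. The level does not show that the signal comes from Etv4. The probe set with the lower mean signal also differed between wild-type tumours and normal glands (limma adjusted p = 0.0142, lost in 2 of 24 alternative fits). Those arrays shared no scan day and differed in GAPDH ratio, so background may differ between them too and that difference alone cannot decide. The probe set with the higher mean signal did not differ (log2 -0.18, limma adjusted p = 0.771). A probe set outside the deleted part stays open, since the probe set with the higher mean signal differed by -0.22 between the genotypes and no source used here gives the deleted part. An exchange of samples stays open: 1 tumour sample, PEA3-null 1, correlated better with the other genotype (by a difference in mean r of -0.04), but no wild-type sample did, as an exchange between the groups would need, and the genotypes correlate almost as well with each other as within themselves.

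Among control probe sets, which no comparison used, 18S ribosomal RNA was 9.94-fold higher in tumours than in normal glands on chip A, 8.75-fold on chip B and 12.2-fold on chip C. The PEA3-null array on chip C, compared by genotype only in an alternative fit, had 94 probe sets at least 4-fold outside all other arrays of that chip. It was the only array of its group there, and every other array had a partner of its group, so their counts are no measure of what is unusual.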

How the results depend on the processing

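The fits on chip A tumour arrays of the shared scan day and those without normal glands 1 and 2 were chosen after seeing the data. The 37 probe sets between the genotypes became 23 with signals floored at 32, 15 without a filter, 5 with only the groups compared, 4 without a variance trend, 3 with array weights, 3 with the replicate number as a block, 63 with chip C added and 6 on chip A within the scan day; the last holds fewer arrays and probe sets, and for the others the cause was not tested. Leaving out a sample gave 3 to 241. Same-numbered samples correlated at -0.09 to 0.02 in their deviations, so the numbers do not pair them. With scan day as a random block the count was 26, but this block cannot separate scan day from genotype. On chip A all tumour arrays shared a day, and on chip B each scan day held tumours of a single genotype. Wild-type tumours against normal glands gave 3525 on chip A alone, where fewer probe sets are tested, 2093 without normal glands 1 and 2, which leaves fewer samples, 5190 with the replicate block and 4144 to 6589 without single samples. PEA3-null tumours against normal glands gave 3029, 1709, 3863 and 3432 to 4914. Etv4 between the genotypes ran from -0.42 to 0.40 without single samples at the probe set higher in tumours and from -0.65 to 0.08 at the other. List tests past the threshold went from 29 to 0 with an estimated correlation in camera (19 at an unadjusted p under 0.05), for which the cause was not tested, and were 27 to 32 without single samples. Shared calls numbered 2706 to 3545 without single samples. Between the genotypes, milk genes had a median of 0.26 without PEA3-null tumour 1 and -0.29 without tumour 2, and oxidative phosphorylation genes -0.16 and 0.23; each fit rests on a lone PEA3-null sample, and the cause was not tested. Over named genes and alternatives, 8100 values stayed on their side of the threshold, 293 no longer passed, 34 newly passed, and 0 that passed in either fit turned direction. Of the 293, 210 belonged to the comparison between the genotypes, where 19 of the 20 named genes that passed missed the threshold in some fit. Scan day could not be fitted for wild-type tumours against normal glands. Signals near the filter of 150 limit what can be called.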

Other observations

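The test in this part was set before its result was seen, but the criterion that its interval must clear the bound was added after. Several genes higher in PEA3-null than in wild-type tumours were also high in normal glands. Cpe read 1260 to 1436 in normal glands, 2228 and 1472 in PEA3-null tumours and at most 217 in wild-type tumours. Ifit3 read 350 to 718 in normal glands and at most 140 in wild-type tumours. Some large genotype differences came with a wide spread within the PEA3-null group and did not pass, such as Ltf, the lactoferrin gene (8143 ± 10439, SD, n = 2, log2 3.30, SE 0.84). Both PEA3-null samples still read higher for Ltf than every wild-type sample. Others missed the threshold with less spread, such as Krt19 (log2 2.02, SE 0.38) and Fosl1 (2.22, SE 0.50). Although the labels state sorting for Sca-1, normal glands read 51137 ± 868 for Acta1 and 23827 ± 3193 for Car3 (SD, n = 3 each).

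A hypothesis was that a segment around Etv4, carried along from another mouse strain, may add to the genotype difference. Of 32 genes that passed, 4 lie on the chromosome of Etv4, or 12.5% (95% exact Clopper-Pearson interval 3.51% to 29.0%), against 8.52% of 11743 tested genes (Fisher's exact test, two-sided, p = 0.346). The planned bound against the hypothesis was a share at most 1.5 times that of tested genes with no significant excess. The share met it narrowly, but the interval reaches far above it, so the 32 genes are too few to decide.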
